A study of Homo sapiens with 6 samples.

How the data were processed

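RNA was measured in 6 primary tumours grown as xenografts from the human breast cancer line MDA-MB-231, 3 from control cells and 3 from cells with srGAP1 knockdown. Per the labels, total RNA was isolated with a silica column kit, polyA RNA was sequenced and the libraries were made with a NEBNext Ultra kit; whether the counting used strand is not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be told apart. The submitters' processing notes name STAR and hg19, with no version. How reads of the mouse host were treated is not given in the sources used here, so reads of host cells that align to the human genome can be part of the counts. Groups and replicate numbers were taken from the sample titles.

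The deposited table holds 29147 genes with raw read counts per tumour. Per the file headers it also holds FPKM values, and for each gene and tumour the deposited FPKM equalled the count scaled by the gene length and the column total. The authors' group means, a signal scale of normalised counts, equalled the means of counts divided by median-of-ratios size factors for all 29147 genes (relative tolerance 1e-09). The deposited log2 fold changes differed by at most 0.00196 from those of DESeq2 with a prior on the coefficients. The deposited p-values and adjusted p-values are the authors' own. With adjusted p under 0.05, the authors' deposited table has 2149 genes higher and 2423 lower; 4274 of the genes called here are also called there in the same direction and 0 in the opposite direction. The gene length and annotation columns of the deposited table gave coordinates and types.

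Everything reported was computed from the raw counts. With edgeR 4.0.16 under R 4.3.3, genes were kept by filterByExpr (minimum count 10), which left 14884 and removed 14263 genes holding 0.167% of the counts. Libraries were scaled by TMM, and the groups were compared by the quasi-likelihood test (two-sided) with Benjamini-Hochberg adjustment over all genes tested at 0.05. CPM values are TMM-scaled, log2 CPM uses a prior count of 2, and the standard error is the log2 fold change divided by the square root of F. The biological coefficient of variation was 16.6% and the median log2 fold change of all tested genes 0.01. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom between 12.4 and 31.7. The labels name no batch. The p-values measure the spread between these tumours.

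Gene lists were tested by camera of limma 3.58.1 with a preset correlation of 0.01, for lists with at least 5 tested genes, with Benjamini-Hochberg adjustment over 34 of 36 lists; 11 were called, 3 higher and 8 lower. The same test with an estimated correlation called 0 lists, and 2 lists had an unadjusted p under 0.05; fry, which tests whether a list's genes move on balance one way without comparing them with other genes, called 9. The lists covered, among others, mitosis, S phase, CDK inhibitors, the TGF-beta family and its targets, collagens, other matrix proteins, proteases, invadopodia, srGAPs with SLITs and ROBOs, integrins, mesenchymal, epithelial and dormancy genes, YAP/TAZ, MAPK, immediate-early, hypoxia, glycolysis, interferon, antigen presentation, NF-kB, cholesterol, unfolded protein, ribosomal, respiratory chain, mitochondrial and MYC genes, and markers of host endothelium, myeloid cells, fibroblasts, adipocytes, muscle, blood cells, and mammary epithelium with skin. The lists, tests, other settings and the rule for named genes were fixed before the data were examined. That rule names SRGAP1 and the TGF-beta ligands, the 10 protein-coding genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 50 counts and no overlap of the groups, and up to 4 members of each list by adjusted p; 2 by p where none was called. Some genes and 1 gene list that this rule or the tests cover are not reported here. Other list members named were chosen after their values were seen. Counts of list members are given over all genes tested and adjusted over the list alone. Members were matched by symbol. The lists name CCN1 and CCN2, whereas the deposited table uses older symbols such as WISP1, so such members can be missing by name. Without a count filter, 22 of 24 YAP/TAZ targets, 33 of 34 TGF-beta response genes and 39 of 41 other matrix genes were found.

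The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter beyond a count above 0, a mean of at least 50 counts, the replicate number as a block, each tumour left out, and host marker genes left out; fold changes relative to chromosome medians were added afterwards. The gene test was tested on 5 sets of simulated counts with 14625 to 14647 genes tested. Each set held 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. The test recovered 16.7% of 1.5-fold, 63.3% of 2-fold and 88.8% of 4-fold changes. Of 618 calls, 9.2% were unchanged genes, above the nominal level. Far more genes, 4671, were called in the tumours, so these shares need not carry over to them. GC content was taken by gene ID from another annotation for 97.4% of tested genes. Total counts per tumour were 15717935, 15160633 and 15403688 in the controls and 14963817, 13604008 and 14630400 in the knockdown tumours. Counting intervals cover counting error only.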

Results

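Bulk RNA sequencing was used to compare primary tumours grown as xenografts from MDA-MB-231 cells, an established human breast cancer cell line that lacks the oestrogen receptor. The series holds 3 control tumours and 3 tumours of cells with knockdown of srGAP1, a protein that acts downstream of the SLIT and ROBO guidance proteins. Its design text calls the 3 tumours of each group biological replicates, and the labels do not say whether the tumours of a group came from the same engineered cell population. The deposited gene counts summed to between 13604008 and 15717935 per tumour. The comparison asked which transcripts differ between the knockdown and the control tumours, and 14884 genes with enough counts were tested.

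SRGAP1, the targeted gene, was examined first, in every library. It lies on chromosome 12 from 64238073 to 64541613 on the plus strand of hg19 (ENSG00000196935). The control tumours 1 to 3 held 629, 549 and 623 of its counts, and the knockdown tumours 1 to 3 held 441, 231 and 327. Its normalised expression was 38.8 ± 1.90 CPM (counts scaled to library size) in the controls (SD, n = 3) and 23.0 ± 6.19 CPM in the knockdown tumours (SD, n = 3). The log2 fold change was -0.75 (SE 0.185), with an edgeR adjusted p of 0.0123, and the 3 knockdown values lay below the 3 control values. Relative to the control mean, 75.3% of the transcript was left in knockdown tumour 1, 43.5% in tumour 2 and 59.1% in tumour 3. The tested genes of chromosome 12 had a median log2 fold change of -0.22. Relative to that median, a setting chosen after the data were examined, SRGAP1 stood at -0.53 with an edgeR adjusted p of 0.0583. The segment from 60000001 to 70000000, which holds SRGAP1, had a lower median of -0.44 over 40 genes, and SRGAP1 at -0.75 lay below it. SRGAP1 was not tested relative to that segment, so the value of -0.53 can include a shift shared with nearby genes. The authors' deposited table gives SRGAP1 a log2 fold change of -0.73.

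**Figure D1:**
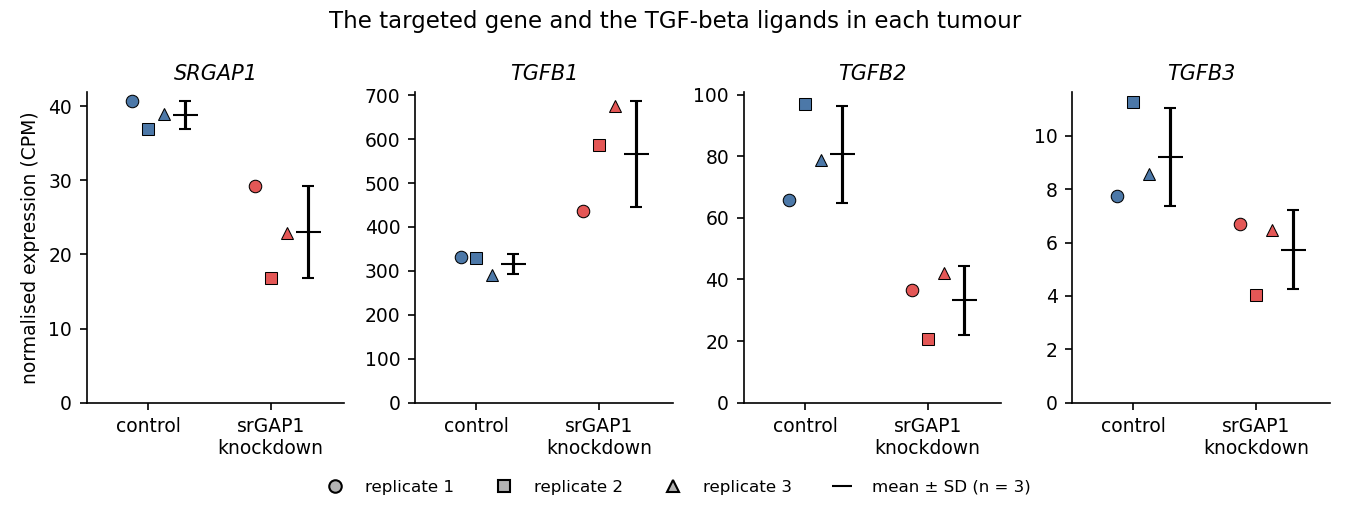
Normalised expression in CPM (y axes, from 0) of SRGAP1, TGFB1, TGFB2 and TGFB3 in 3 control and 3 srGAP1 knockdown tumours; each symbol is 1 tumour and the bars are the mean ± SD (n = 3). SRGAP1 and TGFB2 lie lower and TGFB1 higher in every knockdown tumour than in every control tumour, and TGFB3 did not pass the test.

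The knockdown tumours differed widely from the controls. They had lower expression of interferon response genes, antigen presentation genes, and NF-kB targets and cytokines. Levels of YAP/TAZ targets and cholesterol synthesis genes were higher. These 5 lists were called by camera at the preset correlation, and had adjusted p between 0.604 and 0.723 with an estimated correlation. The hypoxia markers CA9 and EGLN3 were lower, but 18 of the 28 tested hypoxia genes were not called. Among TGF-beta ligands, TGFB1 was 1.79-fold higher and TGFB2 was 2.43-fold lower. By edgeR, 4671 genes passed the threshold, of which 2286 were higher and 2385 lower in the knockdown tumours. Without control 1, control 2 or knockdown 3, the number higher was 1479, 1274 and 1327. A change of at least 2-fold was seen for 666 of the genes that were higher and 1034 of those that were lower, and a change of at least 8-fold for 51 and 187. The groups did not overlap for 6963 genes, or 46.8% of those tested, against 10% by chance for 3 against 3.

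The libraries within a group were not equally alike. The first principal component, with 72.5% of the variance, separated the groups, and knockdown tumour 1 stood apart on the second, with 10.5% of the variance. Across genes, the mean correlation of log2 CPM with the controls was 0.952 for knockdown tumour 1, 0.927 for tumour 2 and 0.936 for tumour 3, where genes are not independent replicates.

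The 10 protein-coding genes with the largest rise among well-expressed genes were VAT1L, LRRC15, TP53I11, RIMS2, COBL, GAL, C6orf15, TMPRSS2, LRRN4 and SNCAIP. TMPRSS2, a transmembrane serine protease, rose from 1.49 ± 0.288 to 29.6 ± 3.44 CPM (SD, n = 3 each; log2 fold change 4.30, SE 0.205). TP53I11, a gene named for its induction by p53, rose from 1.41 ± 0.631 to 37.9 ± 5.11 CPM (log2 fold change 4.74, SE 0.286). LRRC15, a leucine-rich repeat membrane protein, rose from 0.410 ± 0.132 to 12.5 ± 2.83 CPM (log2 fold change 4.90, SE 0.315), and COBL, an actin nucleator, rose by 4.56 (SE 0.435) on the log2 scale. The neuropeptide gene GAL rose by 4.52 (SE 0.488) and the presynaptic scaffold gene RIMS2 by 4.71 (SE 0.596). VAT1L reached 48.7 CPM in knockdown tumour 1 against 3.14 and 1.90 CPM in the other two, and its log2 fold change of 5.09 (SE 1.24) became 2.26 without that tumour; its call was lost without control 1 (0.0521), without control 3 (0.0595) and with limma-voom (0.0959).

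The 10 largest falls were those of FOXR2, MUC5AC, ZBP1, HSH2D, KIAA1644, CMPK2, IGFBP2, GYPC, WISP1 and RSAD2. FOXR2, a forkhead transcription factor gene on chromosome X, had 118, 116 and 99 counts in the controls and 1, 0 and 0 in the knockdown tumours, so that the level was 311 times higher in the controls (95% counting interval 55.4 to 12300). MUC5AC, a secreted gel-forming mucin, went from 19.7 ± 10.2 to 0.141 ± 0.0723 CPM (SD, n = 3 each; log2 fold change -7.06, SE 0.541). The interferon-inducible genes ZBP1, CMPK2 and RSAD2 had log2 fold changes of -6.96 (SE 0.488), -6.14 (SE 0.397) and -5.36 (SE 0.396). IGFBP2, which binds insulin-like growth factors, had a log2 fold change of -5.85 (SE 0.507), and WISP1, a matricellular CCN family member, of -5.45 (SE 0.554).

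The interferon response showed the most uniform change of all lists. Of its 40 tested members, 39 fell, 0 rose and IRF1 was not called (log2 fold change -0.19). The same 39 were reached by the count adjusted over the list alone. The median log2 fold change was -2.61, that is 6.12-fold lower, and the list's summed expression went from 9345 to 1770 CPM. The interferon-induced gene HERC6 went from 170 ± 21.2 to 23.1 ± 1.67 CPM (SD, n = 3 each; log2 fold change -2.89, SE 0.133). IFIT1 and IFI44, which act against viral RNA and viral replication, had log2 fold changes of -3.05 (SE 0.164) and -2.50 (SE 0.136), and PARP9, an interferon-induced ADP-ribosyltransferase, of -2.56 (SE 0.140). The transcription factor genes STAT2, IRF7 and IRF9 had log2 fold changes of -1.25, -2.55 and -1.35. The list medians of the knockdown tumours 1 to 3 lay at -2.73, -2.79 and -2.57 relative to the controls. Camera placed the list below other genes with an adjusted p of 6.79e-28 at the preset correlation; the call was lost with adjusted p = 0.604 with an estimated correlation. IFITM1, IFITM2 and IFITM3 are near-identical genes, and their counts may be split between copies.

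Antigen presentation genes fell alongside. Of 19 tested members, 15 fell and 0 rose, with a median log2 fold change of -0.94, and the count adjusted over the list alone was also 15. The class I peptide transporter TAP1 had a log2 fold change of -1.14 (SE 0.155), the immunoproteasome subunits PSMB8 and PSMB9 of -0.95 (SE 0.114) and -1.01 (SE 0.132), and the class II gene HLA-DRA of -3.12 (SE 0.415). CIITA, the class II transactivator, and CD74, the invariant chain, had log2 fold changes of -1.44 and -2.08. HLA-E, TAPBP and PSMB10 were among those not called, with log2 fold changes of -0.12, 0.09 and -0.00. The camera adjusted p was 2.21e-05, and adjusted p = 0.723 with an estimated correlation. Reads of HLA genes can be shared between near-identical copies.

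NF-kB targets and cytokines were lower as well, with 17 of 25 tested members fallen, 0 risen and a median log2 fold change of -1.27. The chemokine CCL5 had a log2 fold change of -5.28 (SE 0.423), the adhesion receptor ICAM1 of -1.85 (SE 0.227), the apoptosis inhibitor BIRC3 of -1.27 (SE 0.144) and the NF-kB inhibitor NFKBIA of -1.06 (SE 0.158). The cytokine genes IL6, IL8, IL1A, CXCL1 and CSF3 had log2 fold changes of -4.13, -3.38, -3.34, -3.22 and -4.09. Adjusted over the list alone, 17 fell. The list separated the controls from each other: its median lay at 0.47 in control 2 and -0.79 in control 3 relative to the other controls, and 11 members fell without control 2, with a median of -0.83, and 10 without knockdown 3. The camera adjusted p was 0.000179, and adjusted p = 0.723 with an estimated correlation.

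Markers of host myeloid cells moved in the same direction as these immune-related lists. Of 21 markers 6 were tested, 0 rose, and LAPTM5, CTSS and CYBB fell with log2 fold changes of -2.32 (SE 0.170), -0.92 (SE 0.178) and -2.03 (SE 0.499). CYBB lies on chromosome X and stood at -1.435 relative to the median of that chromosome (edgeR adjusted p 0.0607). Adjusted over the list alone, 4 fell, and 5 fell without knockdown 1. The camera adjusted p was 0.00695, and adjusted p = 0.604 with an estimated correlation. Transcripts of 11 leukocyte genes including PTPRC, CD53 and TYROBP summed to 2.61 CPM in the controls. The myeloid list summed to 259.6 CPM in the controls and 66.27 CPM in the knockdown tumours. LAPTM5 alone held 92.2% of the CPM that the tested markers lost. Whether these transcripts came from host or tumour cells was not measured.

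**Figure D2:**
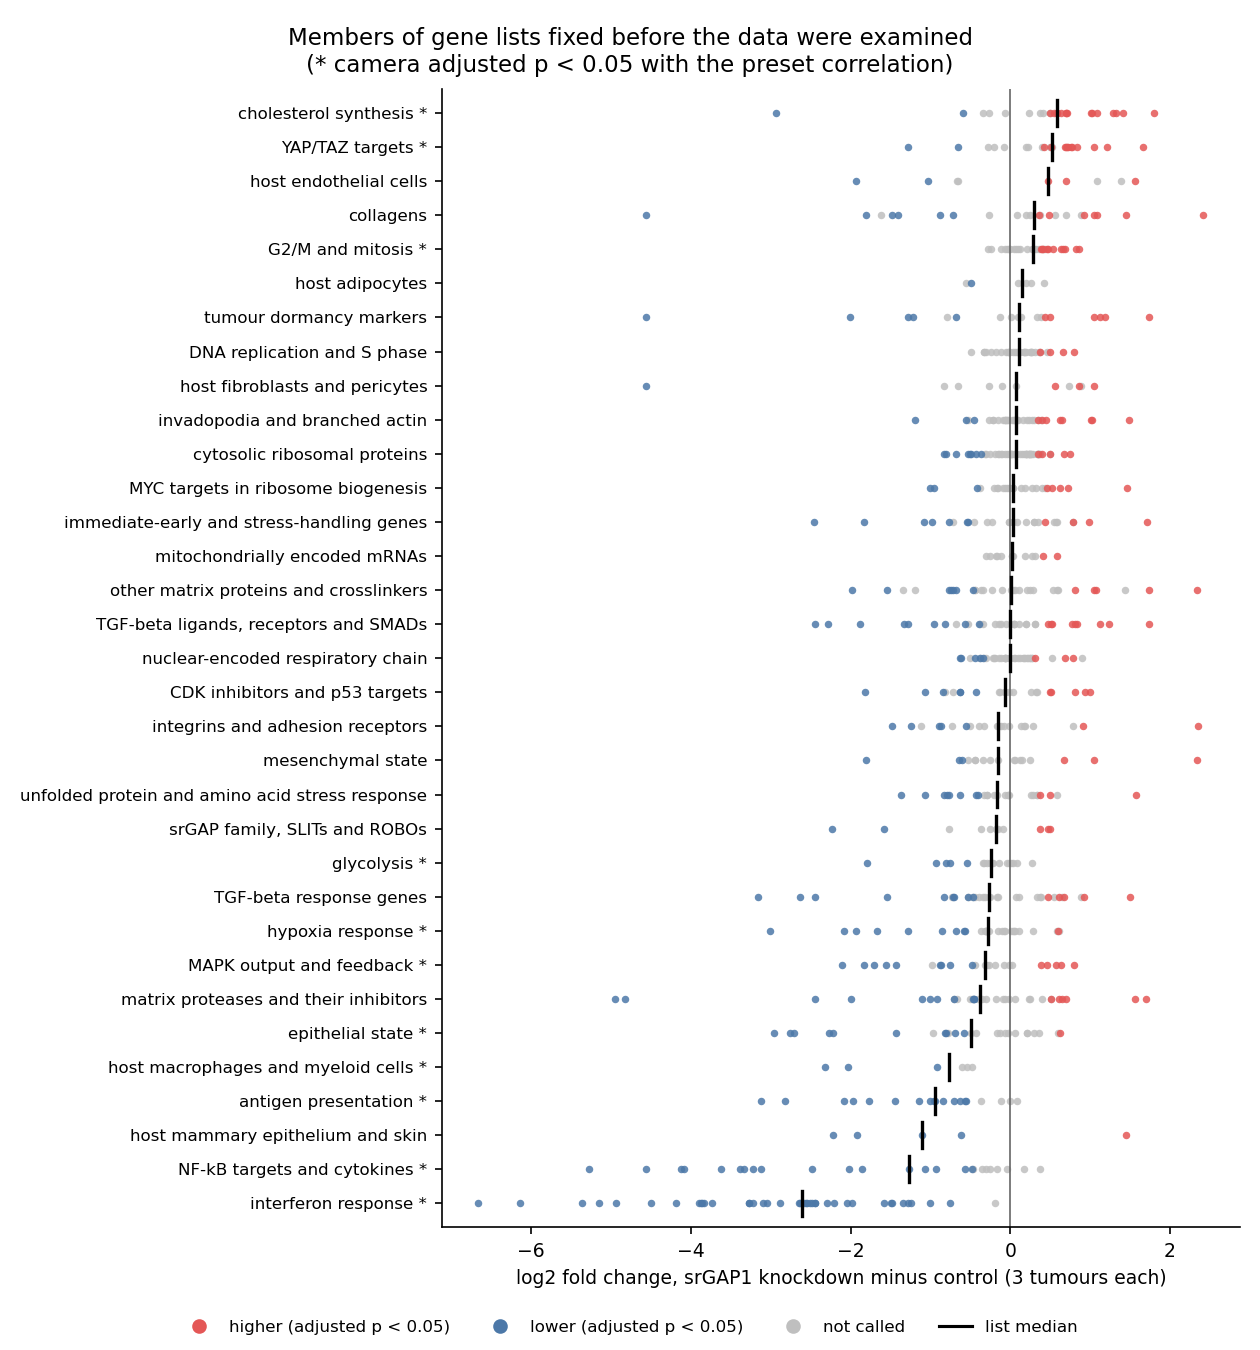
Log2 fold changes (x axis, knockdown minus control, 3 tumours each) of the tested members of gene lists (rows); each point is a gene, coloured where it passed the edgeR test, and the black bar is the list median. The interferon response list has the lowest median, -2.61, and cholesterol synthesis the highest, 0.59.

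YAP/TAZ targets were higher: 12 of 22 tested members rose, 2 fell, and the median log2 fold change was 0.52. The receptor tyrosine kinase AXL went from 875 ± 107 to 1818 ± 285 CPM (SD, n = 3 each; log2 fold change 1.06, SE 0.156). WWC1, an upstream Hippo pathway scaffold, rose by 1.66 (SE 0.150), tissue factor F3 by 1.22 (SE 0.164) and the phosphatase PTPN14 by 0.84 (SE 0.121) on the log2 scale. The 2 members that fell were TGFB2 and IGFBP3. Of the 24 genes of the list, 22 were found by symbol also without a count filter. CCN1 and CCN2 can be missing by name. Adjusted over the list alone, 15 rose and 2 fell. At the preset correlation the list had a camera adjusted p of 0.00320, and adjusted p = 0.723 with an estimated correlation.

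Cholesterol synthesis genes rose for 15 of 24 tested members, with 2 lower and a median log2 fold change of 0.59. HMGCS1, an early enzyme of the pathway, rose by 1.32 (SE 0.139) and INSIG1, a sterol-regulated protein, by 1.01 (SE 0.144) on the log2 scale. TM7SF2, a sterol reductase, and MSMO1 went the other way, with log2 fold changes of -2.93 (SE 0.162) and -0.59. The count adjusted over the list alone was 15 higher and 2 lower. As a list they had a camera adjusted p of 0.00264 at the preset correlation, and adjusted p = 0.723 with an estimated correlation.

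Some mitotic genes rose modestly. The list median of control 1 relative to the other controls, 0.23, lay near those of the knockdown tumours, 0.27, 0.29 and 0.34. Of 32 tested members 11 rose and 0 fell, with a median log2 fold change of 0.29, and 11 rose when adjusted over the list alone. The checkpoint kinase BUB1 rose by 0.67 (SE 0.138) on the log2 scale and the kinetochore gene NDC80, on chromosome 18, by 0.86 (SE 0.184), while TOP2A and CCNB1 were not called, at -0.28 and 0.07. Tested against other genes, the list reached a camera adjusted p of 0.00750, and adjusted p = 0.939 with an estimated correlation, and 0.175 without control 2. Without control 2 (median 0.18) or without knockdown 3, 2 members rose, and relative to chromosome medians, 3. DNA replication genes were not called as a list, with 4 of 34 higher, 0 lower and a camera adjusted p of 0.257, which became 0.0216 without control 1; adjusted over the list alone 2 were higher, as without knockdown 2, and 1 was higher without control 2 or knockdown 3. Thymidylate synthase TYMS, on chromosome 18, rose by 0.80 (SE 0.145). Relative to the median of that chromosome, NDC80 stood at 0.26 and TYMS at 0.19, with edgeR adjusted p of 0.330 and 0.352.

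Hypoxia response genes were lower for 9 of 28 tested members and higher for 1, with a median log2 fold change of -0.28. CA9, a carbonic anhydrase induced by hypoxia, went from 123 ± 33.9 to 15.2 ± 2.38 CPM (SD, n = 3 each; log2 fold change -3.01, SE 0.219). CA12 had a log2 fold change of -1.67 (SE 0.144) and EGLN3, an oxygen-sensing hydroxylase, of -2.08 (SE 0.222). Other members were near 0, among them BNIP3 at -0.15, EGLN1 at -0.07 and P4HA1 at 0.06. The count adjusted over the list alone was 9 lower and 1 higher; 3 were higher without knockdown 1 and 2 without control 2, and the median was -0.18 without control 3. Camera gave an adjusted p of 0.0256 for the list, and adjusted p = 0.939 with an estimated correlation, and the call was lost without control 2 (0.0941), control 3 (0.0594) or knockdown 1 (0.165). Among glycolysis genes 5 of 18 fell and 0 rose, also when adjusted over the list alone. ALDOC, PGK1, SLC16A3 and GAPDH had log2 fold changes of -1.80 (SE 0.203), -0.92 (SE 0.168), -0.81 (SE 0.147) and -0.76 (SE 0.162). PGK1 lies on chromosome X and stood at -0.32 relative to the median of that chromosome (edgeR adjusted p 0.184). The glycolysis list's camera adjusted p was 0.0332, with adjusted p = 0.723 with an estimated correlation, and it was lost without control 2 (0.0927), knockdown 1 (0.115) or knockdown 2 (0.0577) and relative to chromosome medians (0.0714), where 3 members fell.

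Epithelial genes were lower for 10 of 25 tested members and higher for 1, the desmosomal cadherin DSG2. The mucin MUC1 had a log2 fold change of -2.76 (SE 0.223), the basal keratins KRT17 and KRT14 of -2.71 (SE 0.429) and -2.22 (SE 0.374), and the epithelial transcription factor ELF3 of -2.96 (SE 0.533). CDH1, EPCAM, KRT8 and KRT18 were not called, at -0.17, -0.13, -0.07 and 0.29. Adjusted over the list alone, 12 were lower and 2 higher, and 3 were higher without knockdown 1 or knockdown 2. At the preset correlation the list had a camera adjusted p of 0.0405, and adjusted p = 0.939 with an estimated correlation, and it was lost without control 1 (0.0666), control 2 (0.113), knockdown 1 (0.0584), knockdown 2 (0.0912), where 6 members were lower, or the host marker genes (0.0623), and with genes of a mean of at least 50 counts (0.0903). Markers of host mammary epithelium and skin, which share KRT14 with this list, had 4 of 5 lower, 1 higher, also adjusted over the list alone, and a median log2 fold change of -1.11 (camera adjusted p 0.222, fry adjusted p 0.0158). Mesenchymal genes were not called as a list (3 of 17 higher, 3 lower, also when adjusted over the list alone; camera adjusted p 0.880); 7 were lower without knockdown 1, and 1 without control 1, control 2, knockdown 2 or knockdown 3. Within that list SPARC, a matricellular glycoprotein, rose by 2.34 (SE 0.346), and the cadherin CDH11 had a log2 fold change of -1.81 (SE 0.451), which became -2.73 without knockdown 1.

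The MAPK output and feedback list went down with 9 members lower and 5 higher of 23. The immediate-early transcription factor EGR1 had a log2 fold change of -1.83 (SE 0.138), the ERK phosphatase DUSP4 of -1.43 (SE 0.138) and the feedback inhibitor SPRY1 of -1.71 (SE 0.203), while the phosphatase DUSP5 rose by 0.80 (SE 0.105). Adjusted over the list alone, 10 were lower and 5 higher; 3 were higher without control 2, 2 without control 3 or knockdown 2, and 1 without knockdown 3. As a list they had a camera adjusted p of 0.0477 at the preset correlation, and adjusted p = 0.723 with an estimated correlation; it was lost without control 2 (0.0941), control 3 (0.0545), knockdown 1 (0.0584), knockdown 2 (0.0642) or knockdown 3 (0.0617). Immediate-early and stress-handling genes were not called (4 of 27 higher, 7 lower; adjusted over the list alone 4 and 8; camera adjusted p 0.783), and their median of 0.03 and mean of -0.08 differ in sign; without control 1, 4 were lower, and the number higher went from 1 without control 1 or control 2 to 7 without knockdown 1. KLF4 and EGR2 had log2 fold changes of -0.98 (SE 0.110) and -2.46 (SE 0.330).

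Ligands, receptors and SMADs of the TGF-beta family went both ways, with 9 of 34 higher, 9 lower and a camera adjusted p of 0.876; adjusted over the list alone 9 were higher and 10 lower, and relative to chromosome medians 3 and 8. TGFB1 (chromosome 19, 41807492 to 41859816) rose from 316 ± 22.9 to 567 ± 121 CPM (SD, n = 3 each; log2 fold change 0.84, SE 0.163, edgeR adjusted p 0.00409). TGFB2 (chromosome 1, 218519577 to 218617961) fell from 80.7 ± 15.7 to 33.2 ± 11.1 CPM (log2 fold change -1.28, SE 0.238, edgeR adjusted p 0.00322). TGFB3 stood at 9.20 ± 1.85 and 5.73 ± 1.48 CPM and was not called (log2 fold change -0.68, SE 0.245, edgeR adjusted p 0.0573; 0.0280 without knockdown 1). THBS1, which activates latent TGF-beta, rose by 1.74 (SE 0.163). The inhibitory SMAD6 had a log2 fold change of -2.45 (SE 0.203) and the receptor BMPR1B of -2.28 (SE 0.280). SMAD2, on chromosome 18, rose by 0.81 (SE 0.132), and stood at 0.21 relative to the median of that chromosome (edgeR adjusted p 0.271). TGF-beta response genes were not called as a list (5 of 33 higher, 9 lower; adjusted over the list alone 7 and 9; camera adjusted p 0.303), and the number higher went from 2 without control 1, control 2 or knockdown 3 to 8 without knockdown 2. ID1 and ID3, which also respond to BMP, had log2 fold changes of -2.63 (SE 0.186) and -3.15 (SE 0.354). PMEPA1 fell by 0.82 (SE 0.142), and the sphingosine kinase SPHK1 rose by 1.50 (SE 0.213). Of the 34 genes of the response list, 33 were found by symbol also without a count filter, and CCN2 can be missing by name.

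Matrix genes changed in both directions without a call for any of their lists. Of 22 collagens 7 rose and 6 fell, adjusted over the list alone 7 and 7, and the camera adjusted p was 0.665; the median of 0.30 and the mean of -0.09 differ in sign, and without control 3, 4 rose with a median of 0.19; relative to chromosome medians the median was 0.04. COL12A1 rose by 2.42 (SE 0.147), while COL6A1, the most abundant, had a log2 fold change of -1.48 (SE 0.183) and COL3A1 of -4.56 (SE 0.584). Other matrix proteins and crosslinkers had 5 of 31 higher and 7 lower, as they did adjusted over the list alone, with a camera adjusted p of 0.907, and here too the median of 0.01 and the mean of -0.01 differ in sign; without knockdown 1, 8 were higher and 11 lower, and without control 2 or knockdown 3, 3 were higher. Matrix proteases and their inhibitors had 6 of 34 higher and 11 lower, adjusted over the list alone 6 and 12 (camera adjusted p 0.222). The collagenase MMP13 had a log2 fold change of -4.95 (SE 0.633), which became -7.70 without knockdown 1, and the sheddase ADAM8 of -1.11 (SE 0.135), whereas ADAMTS12 rose by 1.70 (SE 0.229).

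Invadopodia and branched actin genes had 8 of 34 higher and 3 lower, as they did adjusted over the list alone (camera adjusted p 0.352, fry adjusted p 0.00645); without knockdown 3, 5 were higher and 1 lower, and relative to chromosome medians 4 and 1. The adaptor NCK2 rose by 1.49 (SE 0.133), and the actin bundler FSCN1 had a log2 fold change of -1.19 (SE 0.155). In the srGAP, SLIT and ROBO list 3 of 11 were higher and 2 lower, adjusted over the list alone 3 and 3 (camera adjusted p 0.422); without control 2, control 3 or knockdown 3, 1 was higher, and without knockdown 1, 4 were lower. The receptor ROBO1 had a log2 fold change of -2.23 (SE 0.181) and its ligand SLIT2 of -1.58 (SE 0.346). SRGAP2 and its partial copies SRGAP2B and SRGAP2C, which can share reads, were not called, at -0.15, -0.18 and -0.09.

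Integrins and adhesion receptors had 2 of 23 higher and 5 lower, as they did adjusted over the list alone (camera adjusted p 0.303); 3 were lower without control 2 and 8 without knockdown 1. L1CAM, a neural adhesion molecule, rose by 2.36 (SE 0.335) although it lies on chromosome X, and ITGA1 and MCAM had log2 fold changes of -1.48 (SE 0.262) and -1.25 (SE 0.124). Dormancy markers went both ways, with 6 of 18 higher and 5 lower, adjusted over the list alone 7 and 5 (camera adjusted p 0.783; median 0.12 and mean -0.20). BHLHE41 had a log2 fold change of -1.22 (SE 0.156). CDK inhibitors and p53 targets had 5 of 22 higher and 6 lower, also adjusted over the list alone (camera adjusted p 0.835): CDKN1A, the p21 inhibitor, had a log2 fold change of -1.07 (SE 0.133), while GADD45A and CDKN1C rose by 0.94 (SE 0.112) and 0.999 (SE 0.202). Without control 1, control 2 or knockdown 2, 3 of that list were higher.

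Lists of general cell functions were not called. The unfolded protein and amino acid stress list had 3 of 25 higher and 8 lower, adjusted over the list alone 4 and 9 (camera adjusted p 0.312); without control 2 or knockdown 2, 4 were lower, and without control 1 or knockdown 3, 5; 0 were higher without control 3, and 1 without control 1, control 2 or knockdown 3. MYC targets in ribosome biogenesis had 5 of 25 higher and 3 lower, also adjusted over the list alone (camera adjusted p 0.593; 3 higher without control 2 or knockdown 3), and MYC itself rose by 1.46 (SE 0.173). Ribosomal proteins had 5 of 54 higher and 8 lower, adjusted over the list alone 4 and 7 (camera adjusted p 0.783); without control 2, 4 were lower, and without knockdown 2 or knockdown 3, 5, while the number higher went from 1 without knockdown 3 to 12 without knockdown 1; relative to chromosome medians 3 were higher and 2 lower. Respiratory chain genes had 3 of 39 higher and 5 lower, adjusted over the list alone 2 and 4 (camera adjusted p 0.980; median -0.00 and mean 0.01); 2 were lower without control 2, and 3 without control 1 or any 1 knockdown tumour. Mitochondrially encoded mRNAs had 2 of 13 higher and 0 lower, adjusted over the list alone 1 and 0 (camera adjusted p 0.783; 0 higher without control 1 or knockdown 3).

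Markers of other host cells were not called as lists. Endothelial markers had 3 of 9 tested genes higher and 2 lower, adjusted over the list alone 5 and 2 (camera adjusted p 0.699; 5 higher without control 1), and fibroblast and pericyte markers had 3 of 11 higher and 1 lower, adjusted over the list alone 4 and 1 (camera adjusted p 0.876; median 0.07 and mean -0.20; 0 higher without control 2, knockdown 3 or relative to chromosome medians, and 1 without control 3). Adipocyte markers had 0 of 6 higher and 1 lower, also adjusted over the list alone (camera adjusted p 0.928; median 0.15 and mean -0.01). Of the skeletal muscle markers 3 were tested and 0 called, and of the red cell, neutrophil and lymphocyte markers 0 were tested.

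**Figure D3:**
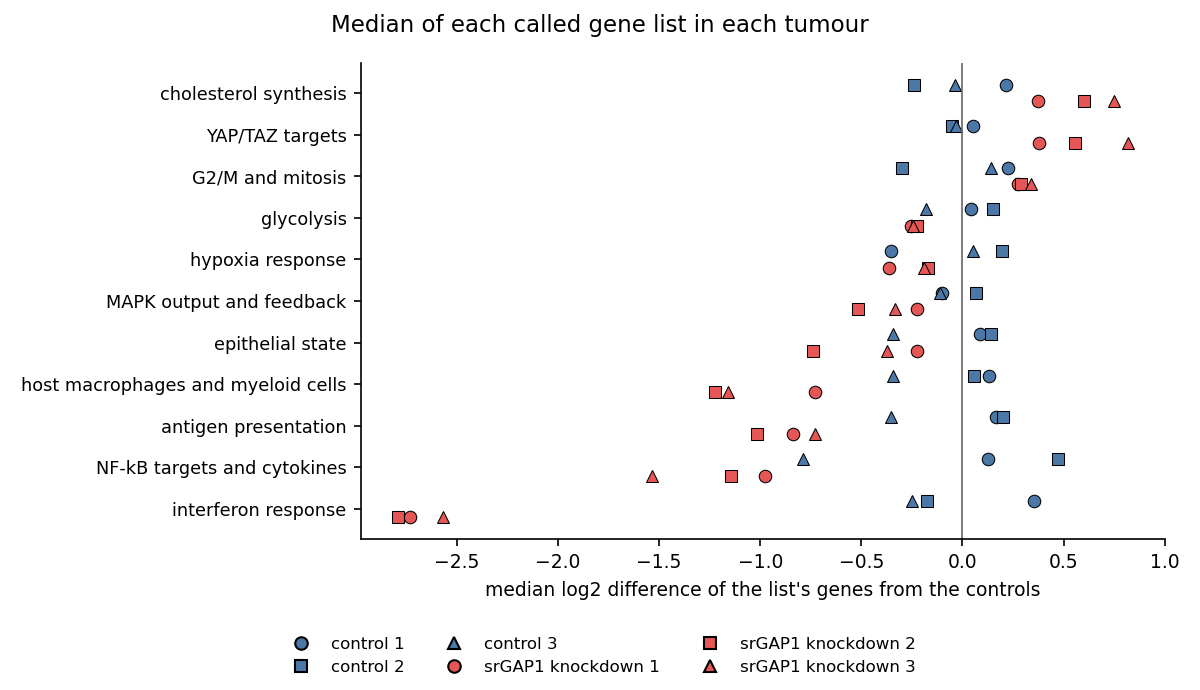
Median log2 difference of each called list's genes from the controls (x axis) in each of the 6 tumours (symbols); a control is compared with the other controls. The interferon medians of the knockdown tumours lie between -2.79 and -2.57, while for hypoxia control 1, at -0.35, lies beside the knockdown tumours.

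Expression also shifted along most of the length of some chromosomes. The median log2 fold change was 0.52 over 250 tested genes of chromosome 13, 0.61 over 197 genes of chromosome 18 and -0.60 over 508 genes of chromosome X. On chromosome X, 85.8% of tested genes were lower, and on chromosomes 13 and 18, 79.6% and 86.3% were higher. Smaller shifts stood on other chromosomes, such as a median of -0.29 on chromosome 4, with 77.9% of tested genes lower, and some were confined to segments, such as 0.46 over 164 genes of chromosome 9 from 130000001 to 140000000 and -0.50 over 80 genes of chromosome 14 from 20000001 to 30000000. On chromosome X the shift was -0.23 in knockdown tumour 1, -0.75 in tumour 2 and -0.80 in tumour 3. On chromosome 18, control 3 lay at 0.26 relative to the other controls and control 1 at -0.15, against 0.47 in knockdown tumour 3. Chromosomes 13, 18 and X held 6.42% of the tested genes and 10.8% of the called ones. With each gene taken relative to the median of its chromosome, a setting chosen after the data were examined, 1762 genes were higher and 2097 lower.

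**Figure D4:**
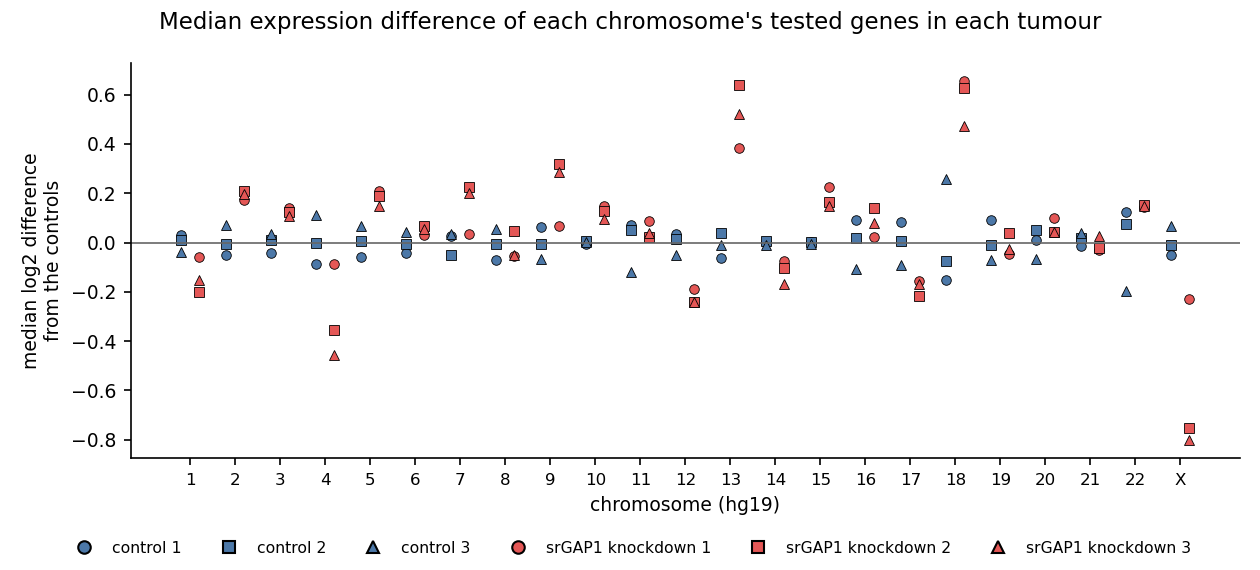
Median log2 difference from the controls (y axis) of the tested genes of each chromosome (x axis, hg19) in each of the 6 tumours (symbols); a control is compared with the other controls. Chromosomes 13 and 18 lie above 0 and chromosome X below 0 in all 3 knockdown tumours, with knockdown tumour 1 nearest 0 on chromosome X at -0.23.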

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

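The alternatives were listed before the data were examined, except the one relative to chromosome medians, chosen afterwards; the pseudocount alternative was not run because the table holds counts. SRGAP1 kept its direction and its call in 13 of 14 alternatives, with log2 fold changes between -0.96 and -0.57 when 1 tumour was left out, and between -0.96 and -0.53 over all 14, with edgeR adjusted p up to 0.0583. Relative to chromosome medians it was -0.53. The subtraction of the chromosome 12 median of -0.22 accounts for the difference. The segment of chromosome 12 from 60000001 to 70000000, which holds SRGAP1, had a lower median of -0.44 over 40 genes. A shift of that segment was therefore not removed in full, and SRGAP1 was not tested relative to it. The number of genes higher ranged from 1274 to 2709 and the number lower from 1683 to 3009 when 1 tumour was left out, and DESeq2 gave 2229 and 2467. The number of gene lists called, 11, ranged from 6 to 11 over the leave-outs and was 0 with camera and an estimated correlation, where each list's own correlation enters the variance. Of the 11, fry called 6 in the same direction, without mitosis (0.192), epithelial (0.119), hypoxia (0.0782), NF-kB (0.0732) and cholesterol (0.0586). Epithelial, MAPK, hypoxia and glycolysis lists lost their call in 3 or more of the leave-outs and the mitosis list in 1, while the interferon, antigen presentation, NF-kB, YAP/TAZ, cholesterol and host myeloid lists lost it in 0. For the named genes 1928 of 2003 values kept their direction and side of the threshold and 0 reversed. TGFB3 passed under 3 alternatives, with log2 fold changes between -0.82 and -0.48 over 14.

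The replicate numbers shared by the groups did not pair the tumours: the deviations of same-numbered tumours from their group means correlated at -0.158, -0.201 and -0.183. With the replicate number as a block, 1557 genes were higher and 1855 lower, SRGAP1 stood at -0.78 and 9 lists were called, without those of MAPK output and glycolysis (0.0580 and 0.0525). Low counts left 14263 genes untested. In simulated data, not split by expression level, 63.3% of 2-fold changes were called. Those data held far fewer changed genes than were called here, so the share need not carry over.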

Other observations

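Histone genes rose as a group that the lists did not hold. They came from camera tests of 219 families of genes sharing the letters of their symbols, chosen after the data were examined. At the preset correlation 5 families were called, HIST and RTN higher and IFI, ZNF and PCDHB lower. With an estimated correlation 0 were called. Of 22 tested protein-coding HIST genes, 14 rose and 0 fell, with a median log2 fold change of 1.11, and all 14 lie on chromosome 6, as do 18 of the 22. HIST1H2BJ, HIST1H2AG and HIST1H2BK rose by 2.32 (SE 0.322), 2.18 (SE 0.275) and 1.68 (SE 0.164) on the log2 scale. Without control 2, knockdown 2 or knockdown 3, 9 rose. Camera gave the family an adjusted p of 7.17e-05, and adjusted p = 0.987 with an estimated correlation. Histone copies are nearly identical, and most of their mRNAs lack a polyA tail, so their counts in a polyA library are uncertain. The 10 Mb bin of chromosome 6 from 20000001 to 30000000 had a median of 0.05 over 73 genes.

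Genes around the interferon pathway, also chosen after their values were seen, changed on both sides. The interferon gene IFNL1 had 45, 17 and 21 counts in the controls and 0, 2 and 1 in the knockdown tumours. The RNA sensor TLR3 and the RNA editing enzyme ADAR had log2 fold changes of -2.54 (SE 0.243) and -1.33 (SE 0.170). The receptor subunit IFNAR2 and the kinase JAK1 rose by 0.79 (SE 0.217) and 0.79 (SE 0.111), and IFNAR1 was not called, at -0.10.

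Of the tests that follow, those of GC content with gene length, of shuffled genes, of depth and of other splits were set before their result was seen; those of host immune cells, chromosome shifts and graded SRGAP1 effect in the interferon list, other population differences, a few strongly changed genes, the tests of copy number and the admixture were chosen after the result was seen.

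The fall of the interferon genes was weighed against the host and the chromosomes. Transcripts of 11 leukocyte genes, picked after the result was seen, came in the controls to 0.0344% of the CPM that the interferon list lost. The CPM lost over the tested myeloid markers came to 2.53%, of which LAPTM5 alone held 92.2%. Host reads are seen here only where they align to the human genome. The level that a loss of host immune cells would need was not measured, so these shares do not decide it. Chromosome-wide shifts did not account for it, since the list's median was -2.75 relative to chromosome medians. A difference between the control and knockdown cell populations other than SRGAP1 cannot be told apart from the knockdown, because the labels tell 1 cell population per group apart. The knockdown itself stays open beside it, and whether its effect is graded cannot be told apart with 3 libraries, as the list median of knockdown tumour 1 minus the mean of the other two was -0.0489 although its SRGAP1 was highest.

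The shifts of chromosomes 13, 18 and X were larger than chance placement of genes gives, with 0% of 1000 shuffles reaching the smallest of the 3 shifts. These 3 chromosomes have the largest shifts in the same data, and the shuffles were read on these 3 only. GC content and gene length did not account for them: at least 87.8% of each shift was kept after adjustment for GC, length and expression. For a few strongly changed genes the test had little room to fail, since such genes hardly move a median. At least 79.6% of the tested genes of each chromosome moved with it. A candidate explanation is a difference in chromosome copy number between the cell populations. Of 30 bins of 10 Mb on these chromosomes, 96.7% had a median of the same sign as their chromosome. The shifts stood in all 3 knockdown tumours. Bins were counted by sign alone on the chromosomes with the largest shifts, so this test had little room to fail and does not decide it. The bin of chromosome 13 from 20000001 to 30000000 stood at only 0.086. That of chromosome X from 1 to 10000000 stood at 0.095, against the direction of its chromosome. Control 3 itself lay at 0.26 on chromosome 18 relative to the other controls, against 0.47 in knockdown tumour 3, and no DNA measurement was analysed here.

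Knockdown tumour 1 lay nearer the controls and kept the most SRGAP1. Admixed control-like cells would need to make up 49.3% of it to give its SRGAP1 level, but 16 genes nearly silent in the other knockdown tumours stood at a median of 0.321% of their control level there. Depth did not account for it, since with all libraries thinned to 13604008 counts its mean correlation with the controls still led by 0.0166. Shifts of whole chromosomes were not its whole source: 87.5% of the lead was kept after each library was centred on its chromosome medians. Such centring leaves shifts confined to segments in place, so copy number of segments was not tested. The centring replaced a first test, whose result had been seen. There the shifts of chromosomes 13, 18 and X in knockdown tumour 1 came to 65.7%, 119% and 29.7% of the other knockdown tumours' mean. A smaller shift of chromosome X therefore stays open as a part. A weaker response at a higher SRGAP1 level is a hypothesis that 1 tumour cannot test.

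The count of 4671 called genes was set against other splits of the 6 tumours into 3 and 3. Of the 10 splits, 1, the real one, gave as many, and the highest count of the others was 0. Each other split mixes control and knockdown tumours, so the difference between them widens its spread and makes few calls likely. The splits therefore do not test chance, and 10 splits are too few for a share under 0.05.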
